A study of Mus musculus with 11 samples.

How the data were processed

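RNA was measured by sequencing in 11 libraries of B16-OVA cells, a mouse melanoma line of C57BL/6J origin that expresses ovalbumin. Per the labels' protocols, the cells were transfected with a control siRNA or with a siRNA pool against YAP and TAZ, the products of Yap1 and Wwtr1. After 48 h they were heated at 45 °C for 1 h and left to recover at 37 °C for 6 h, or were not heated. RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit, per the labels' protocols. The 4 groups held 3 unheated control siRNA libraries, 2 heated control siRNA libraries (replicates 1 and 3), 3 unheated YAP/TAZ siRNA libraries and 3 heated YAP/TAZ siRNA libraries. Replicate 2 of the heated control siRNA cells was not analysed here. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

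The values were FPKM (fragments mapped to a gene, scaled to its length and to the mapped fragments of the library), in 1 gene table that the authors deposited. The submitters' processing notes name Trimmomatic 0.36, HISAT2, SAMtools, StringTie and DESeq2, with no role or order, and the mouse genome build GRCm38. Settings, the annotation release and the strandedness of the counting are not given in the sources used here. The table held 54686 entries. Of these, 54104 had Ensembl gene identifiers, 54038 of which matched a symbol, and 582 were loci assembled by the authors' software without a gene name. The assembled loci held 0.54 to 0.98% of the summed FPKM of a library, and 66 Ensembl identifiers without a match were kept but are not named. Gene positions were taken from GENCODE M21 on GRCm38.

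No read counts came with the FPKM values. The smallest steps between low values gave 30.5 to 43.9 M fragments per library (M, mega), counted as fragments of full weight, so that 1 fragment on a gene of 1 kb was worth 0.0228 to 0.0328 FPKM. Of the values above 0, 0.0% were whole numbers to within 1e-6, and reads could not be recovered because the quantifier divides fragments between transcripts. Count models were therefore not used. Genes that share sequence with near-identical copies (Hspa1a with Hspa1b, ribosomal protein genes with their pseudogenes) and genes that overlap others on either strand are uncertain in such a table.

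Values were analysed as log2(FPKM + 1) for the 12626 genes with at least 1 FPKM in at least 2 libraries. A fold change on this scale understates the change of low genes, and an interaction can be under- or overstated where the siRNAs differ in level without heat. All 11 libraries entered 1 limma fit with a mean per group, no covariate and 7 residual degrees of freedom (limma 3.58.1, R 4.3.3, empirical Bayes with a trend), and p-values were adjusted by the Benjamini-Hochberg method within each of 5 comparisons. The comparisons were heat against no heat under control siRNA and under YAP/TAZ siRNA, the difference between those 2 heat responses (the interaction), and YAP/TAZ siRNA against control siRNA without heat and after heat. Genes with an adjusted p under 0.05 were called. Values after ± are standard errors of a log2 change unless marked SD. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

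Of 30 gene lists, 24 had at least 3 tested members and were tested with camera (limma) at a preset correlation between genes of 0.01, which asks whether a list moved against all other genes. The same test with a correlation estimated per list, and fry (limma), were run beside it, and p-values were adjusted over the lists of a comparison. With an estimated correlation, 1 of 13 list calls held for heat under control siRNA, 0 of 13 for heat under YAP/TAZ siRNA, 4 of 17 for the interaction, 2 of 17 for YAP/TAZ siRNA without heat and 7 of 16 for YAP/TAZ siRNA after heat. Fry asks only whether a list's genes move on balance one way. It called 18, 21, 22, 20 and 22 of 24 lists in the same order of comparisons. It ended the calls of the ribosomal protein genes for heat under control siRNA (adjusted p = 0.358) and of the Hippo pathway components for the interaction (adjusted p = 0.0625). No called list had a median against the direction of its test.

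The groups, the test, the filter, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. That rule took, per comparison, the targeted genes, the 8 highest and 8 lowest called genes whose groups did not overlap, up to 4 members of each list by p-value, and 11 genes of the heat shock and YAP/TAZ responses. One of these 11, Ankrd1, was below the filter and was not tested. One gene is not reported here. Predicted genes, pseudogenes and some loci that overlap larger genes were left unnamed. The 5 comparisons were also run on simulated data in which 200 of 12626 genes changed. At a log2 change of 1, the share recovered was 88.1% for heat under control siRNA, 95.5% for heat under YAP/TAZ siRNA, 74.6% for the interaction, 94.0% for YAP/TAZ siRNA without heat and 89.6% for YAP/TAZ siRNA after heat. False calls made up 6.47, 2.33, 3.50, 3.85 and 2.40% of calls in that order.

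Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 5 FPKM, 3 other scalings (1 total per library, median-of-ratios, quantile normalization), fits without a trend, with robust variances, with only the groups compared, with library weights and with the replicate number as a block, calls that also needed a 2-fold change, and each library left out in turn. A fit without the assembled loci, and the overlap with the heated control libraries divided between its 2 comparisons, were added after seeing the data. The share of genes with a smaller heat response was taken among genes called higher by a mean heat effect weighted 44.4% control siRNA and 55.6% YAP/TAZ siRNA, because choosing genes on the control response alone would make the other response look smaller. Simulations with no interaction, or with unchanged groups, were drawn 100 times, with noise independent between genes.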

Results

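The series asked how YAP and TAZ, transcriptional co-activators of the Hippo pathway that act through TEAD factors, shape the heat shock transcriptome of B16-OVA melanoma cells. Gene-level FPKM values were available for 3 unheated and 2 heated libraries under control siRNA, and for 3 unheated and 3 heated libraries under YAP/TAZ siRNA. Depth was 38.3 to 43.9 M fragments in unheated control siRNA libraries, 34.1 and 36.6 M in heated ones, 39.2 to 41.4 M in unheated YAP/TAZ siRNA libraries and 30.5 to 38.5 M in heated ones. The number of genes above 0 was 20000 to 20365, 23173 to 23242, 20632 to 20914 and 21534 to 21662 in the same order. Correlations of log2 values across genes were 0.977 to 0.984 within groups and 0.900 to 0.958 between groups. Signed values given for single genes below are log2 changes ± standard error. The first principal component (38.7% of the variance) placed the heated control libraries at one end and the unheated YAP/TAZ siRNA libraries at the other.

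Both targeted genes were lower in every YAP/TAZ siRNA library than in any control siRNA library. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, GRCm38) was at 7.26, 5.79 and 15.6 FPKM in unheated and 10.9 and 5.96 FPKM in heated control siRNA libraries. Under YAP/TAZ siRNA it was at 2.75, 3.02 and 2.54 FPKM without heat and 2.61, 2.26 and 2.29 FPKM after heat. Wwtr1, which encodes TAZ (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910), was at 5.37, 6.28 and 8.20 FPKM without heat and 5.50 and 8.47 FPKM after heat under control siRNA. It was at 1.83, 1.83 and 1.65 FPKM and at 1.72, 1.40 and 1.55 FPKM under YAP/TAZ siRNA. Yap1 fell with the siRNA pool without heat (log2 change -1.38 ± 0.30, adjusted p = 0.00445) and after heat (-1.43 ± 0.34, adjusted p = 0.00593), as did Wwtr1 (-1.45 ± 0.16, adjusted p = 6.1e-05, and -1.62 ± 0.17, adjusted p = 6.1e-05). Without heated control replicate 1 the Yap1 change after heat was -1.04 and was no longer called. Neither gene was called for heat or for the interaction, with interaction values of -0.055 for Yap1 and -0.17 for Wwtr1.

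**Figure D1:**
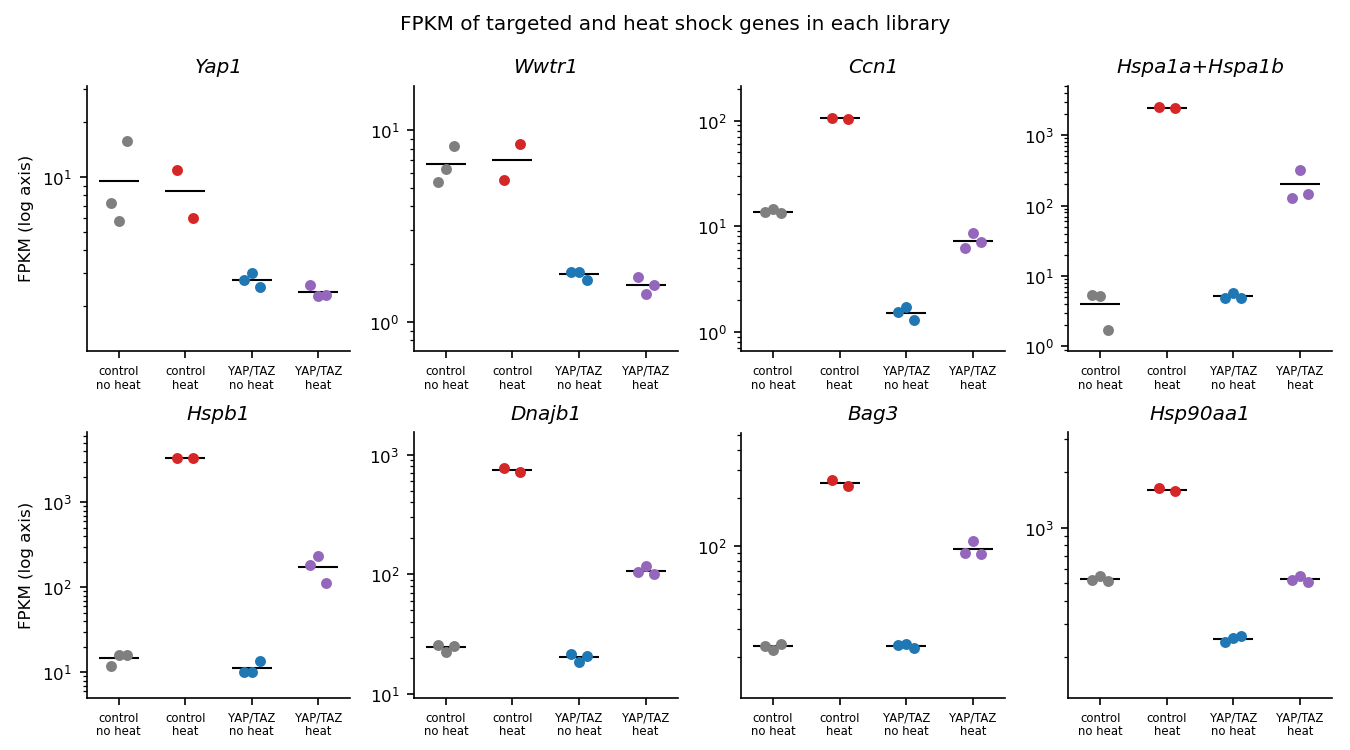
FPKM (log axis) of Yap1, Wwtr1, Ccn1, the sum of Hspa1a and Hspa1b, Hspb1, Dnajb1, Bag3 and Hsp90aa1 in each of the 11 libraries, 1 point per library with a line at each group's mean. The summed Hspa1a and Hspa1b means were 4.07, 2461, 5.15 and 201 FPKM for unheated control, heated control, unheated YAP/TAZ siRNA and heated YAP/TAZ siRNA cells.

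Heat shock in control siRNA cells raised the inducible chaperone genes Hspb1, Hspa1a, Hspa1b, Dnajb1 and Bag3. Hspb1, a small heat shock protein that holds unfolded proteins (ENSMUSG00000004951, chromosome 5, 135887919 to 135889563), rose from 14.7 ± 2.38 FPKM (SD, n = 3) to 3309 ± 17.6 FPKM (SD, n = 2), a log2 change of 7.73 ± 0.27 (adjusted p = 1.3e-07). The inducible Hsp70 genes Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) and Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) rose by 9.30 ± 0.71 (adjusted p = 7.6e-06) and 8.30 ± 0.71 (adjusted p = 1.5e-05). Because these neighbours are nearly identical, their sum is the safer value, and it rose from 4.07 ± 2.05 (SD, n = 3) to 2461 ± 63.9 FPKM (SD, n = 2), by 9.03 ± 0.43 (adjusted p = 5.5e-07). The co-chaperones Dnajb1 (ENSMUSG00000005483, chromosome 8, 83608193 to 83612653) and Bag3 (ENSMUSG00000030847, chromosome 7, 128523616 to 128546981) rose by 4.87 ± 0.09 (adjusted p = 4.2e-09) and 3.37 ± 0.08 (adjusted p = 1.4e-08), Hsph1 by 1.86 ± 0.08 and Hsp90aa1 by 1.61 ± 0.05.

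Of 37 heat shock chaperones tested, 25 rose, 1 fell and 11 were not called (25 and 2 adjusted over the list alone). The chaperones were called as a list (median log2 value 0.59, adjusted p = 7.1e-17, and adjusted p = 0.0338 with an estimated correlation). Most immediate early genes and p53 targets rose beside them, with list calls that ended with an estimated correlation. Immediate early genes (24 tested) included 17 that rose, 3 that fell and 4 not called (17 and 3 adjusted over the list alone). Their median was 1.14 (adjusted p = 4.7e-12, and adjusted p = 0.0804 with an estimated correlation). Atf3, a stress-induced repressor (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), rose by 4.76 ± 0.12 from 1.42 ± 0.267 FPKM (SD, n = 3), Jun by 3.87 ± 0.08 and Btg2, an antiproliferative p53 target (ENSMUSG00000020423, chromosome 1, 134075170 to 134079120), by 3.02 ± 0.09. Of 19 p53 targets tested, 13 rose, 1 fell and 5 were not called (13 and 1 adjusted over the list alone). The median was 0.51 (adjusted p = 5.1e-10, and adjusted p = 0.0804 with an estimated correlation). Trp53inp1 was at 2.48 ± 0.09, Sesn2 at 2.16 ± 0.08 and Mdm2, the ubiquitin ligase of p53 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758), at 1.84 ± 0.06. Integrated stress response genes (23 tested) included 11 that rose, 6 that fell and 6 not called (11 and 6 adjusted over the list alone). Their median was 0.21 (adjusted p = 8.2e-04, and adjusted p = 0.156 with an estimated correlation). Among them were Ddit4 (3.19 ± 0.10) and Ppp1r15a (2.95 ± 0.11). Gadd45g (3.75 ± 0.13) and the phosphatase gene Dusp8 (3.41 ± 0.13) were also among the highest.

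The DNA replication, mitosis, cholesterol synthesis and pigmentation lists were called lower with heat in control siRNA cells, and each of these calls ended with an estimated correlation. Of 24 DNA replication genes tested, 0 rose, 18 fell and 6 were not called (0 and 18 adjusted over the list alone). The median was -0.44 (adjusted p = 9.5e-05, and adjusted p = 0.0804 with an estimated correlation). These included Rrm2, a subunit of ribonucleotide reductase (-1.47 ± 0.06, adjusted p = 2.2e-07), and Uhrf1 (-1.17 ± 0.05). Mitosis genes (24 tested) included 0 that rose, 15 that fell and 9 not called (0 and 15 adjusted over the list alone). Their median was -0.32 (adjusted p = 0.0105, and adjusted p = 0.137 with an estimated correlation). Ccnb1 was at -1.14 ± 0.05. Of 20 cholesterol synthesis genes tested, 0 rose, 17 fell and 3 were not called (0 and 18 adjusted over the list alone). The median was -0.55 (adjusted p = 9.5e-05, and adjusted p = 0.0804 with an estimated correlation). Among them were Nsdhl (-1.08 ± 0.06) and Mvd (-0.92 ± 0.08). Pigmentation genes (19 tested) included 1 that rose, 8 that fell and 10 not called (1 and 9 adjusted over the list alone). Their median was -0.28 (adjusted p = 0.0330, and adjusted p = 0.112 with an estimated correlation). They were led by Tyr, the tyrosinase gene (-1.48 ± 0.07), and the melanocortin receptor gene Mc1r (-1.42 ± 0.05). Lower genes outside the lists' themes were Tspan10 (-2.19 ± 0.09), Lgals3bp (-2.16 ± 0.20) and Lrrc4b (-2.32 ± 0.16). The glucose transporter gene Slc2a1 fell by 1.76, while the hypoxia and glycolysis list that holds it was not called (median log2 value -0.19, adjusted p = 0.920, with 8 of 22 genes lower and 2 higher).

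The replication-dependent histone list had 21 of 70 genes tested, with at most 15.7 FPKM in any library. Its transcripts mostly lack a poly(A) tail, so their values may depend on how RNA was selected. Of 21 replication-dependent histone genes tested, 16 rose, 2 fell and 3 were not called (17 and 2 adjusted over the list alone). The median was 0.63 (adjusted p = 2.1e-07, and adjusted p = 0.0804 with an estimated correlation). Hist1h4f was at 1.56 ± 0.16. Mitochondrially encoded mRNAs (13 tested) included 11 that rose, 0 that fell and 2 not called (11 and 0 adjusted over the list alone). Their median was 0.27 (adjusted p = 7.5e-06, and adjusted p = 0.145 with an estimated correlation). Of 16 NRF2 antioxidant targets tested, 5 rose, 2 fell and 9 were not called (5 and 2 adjusted over the list alone). The median was 0.23 (adjusted p = 0.0107, and adjusted p = 0.112 with an estimated correlation). The heme oxygenase gene Hmox1 was at 1.19 ± 0.07. Chaperonin ring subunits (8 tested) included 4 that rose, 0 that fell and 4 not called (4 and 0 adjusted over the list alone). Their median was 0.12 (adjusted p = 0.0216, and adjusted p = 0.382 with an estimated correlation). Of 84 ribosomal protein genes tested, 14 rose, 1 fell and 69 were not called (4 and 1 adjusted over the list alone). The median was 0.089 (adjusted p = 5.5e-06, and adjusted p = 0.477 with an estimated correlation). YAP/TAZ-TEAD targets were not called as a list (median log2 value -0.069, adjusted p = 0.257, and a median of 0.10 with median-of-ratios scaling and 0.067 with quantile normalization), although Ccn1 (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981) and Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683), matricellular genes commonly used to read YAP activity, rose by 2.85 ± 0.11 and 1.27 ± 0.09. Endoplasmic reticulum stress genes were not called either (median log2 value -0.24, adjusted p = 0.312), with Dnajb9 up by 1.29 ± 0.08 and Sel1l at -0.90 ± 0.07. Few markers of other cell types passed the filter: 1 of 9 fibroblast, 2 of 10 macrophage, 1 of 9 lymphocyte, 0 of 7 endothelial and 0 of 7 keratinocyte markers. They were low, with group means of 0.0768 to 1.85 FPKM for Cd79a and 0.477 to 1.58 FPKM for Pdgfrb. Cd68 was higher after heat by 1.60 ± 0.16 (0.718 ± 0.221 against 4.23 ± 0.846 FPKM, SD) and Cd79a by 1.21 ± 0.11. Pdgfrb was lower at -0.54 ± 0.07, and Lyz2 was not called (0.17 ± 0.11).

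In all, 1560 genes rose and 4654 fell of 12626 tested (475 and 298 by at least 2-fold), with a median log2 change of all genes of -0.16, and 874 or 986 rose without heated control replicate 1 or 3. The split was 2891 higher and 2733 lower with median-of-ratios scaling (median 0.011) and 2337 and 3252 with quantile normalization (median -0.044), and under these scalings the Hsf1 change (-0.17 ± 0.06) turned to 0.014 and 0.022, a call that also ended without any 1 of 7 libraries (each unheated and heated control, unheated YAP/TAZ siRNA replicate 2 and heated YAP/TAZ siRNA replicate 1). Some list calls ended under other scalings (pigmentation and mitosis with median-of-ratios, chaperonin with 1 total or quantile, NRF2, ribosomal protein and mitochondrial mRNA lists with quantile, the last at a median of 0), without a filter (chaperonin, NRF2, integrated stress response), with the filter at 5 FPKM (pigmentation) or without unheated control replicate 1 (pigmentation), and leaving out single libraries gave NRF2 medians down to 0.11 (without heated control replicate 3) and ribosomal protein medians of 0.048 (without that library) to 0.15 (without heated control replicate 1).

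Heat shock in YAP/TAZ siRNA cells also raised the inducible chaperones, with smaller log2 changes than under control siRNA. Hspb1 went from 11.3 ± 2.04 to 175 ± 60.6 FPKM (SD, n = 3 each), a rise of 3.79 ± 0.24 (adjusted p = 8.0e-06), and summed Hspa1a and Hspa1b from 5.15 ± 0.502 to 201 ± 108 FPKM (SD, n = 3 each), a rise of 4.92 ± 0.38 (adjusted p = 2.3e-05). Dnajb1 rose by 2.35 ± 0.08 (adjusted p = 4.0e-07), Bag3 by 1.97 ± 0.07, Hsph1 by 1.27 ± 0.07 and Hsp90aa1 by 1.07 ± 0.05. Of 37 heat shock chaperones tested, 27 rose, 2 fell and 8 were not called (29 and 3 adjusted over the list alone). Their median was 0.42 (adjusted p = 1.7e-13, and adjusted p = 0.0674 with an estimated correlation). Chaperonin ring subunits (8 tested) included 8 that rose, 0 that fell and 0 not called (8 and 0 adjusted over the list alone). The median was 0.46 (adjusted p = 1.1e-06, and adjusted p = 0.104 with an estimated correlation). Cct5 was at 0.58 ± 0.05 and Cct7 at 0.47 ± 0.03. Of 12 mitochondrial chaperones and proteases tested, 7 rose, 0 fell and 5 were not called (7 and 0 adjusted over the list alone). Their median was 0.18 (adjusted p = 5.6e-04, and adjusted p = 0.0965 with an estimated correlation). Among them were the mitochondrial Hsp10 gene Hspe1 (1.66 ± 0.08) and the Hsp60 gene Hspd1 (0.66 ± 0.05).

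The ribosomal protein, proteasome, DNA replication and mitosis lists were called higher in these cells, and no such call held with an estimated correlation. Ribosomal protein genes (84 tested) included 79 that rose, 1 that fell and 4 not called (79 and 1 adjusted over the list alone). The median was 0.76 (adjusted p = 1.4e-29, and adjusted p = 0.155 with an estimated correlation). Examples were Rps2 (0.87 ± 0.08, adjusted p = 5.3e-05) and Rps19 (0.87 ± 0.08). Of 35 proteasome subunits tested, 23 rose, 0 fell and 12 were not called (24 and 0 adjusted over the list alone). Their median was 0.30 (adjusted p = 3.5e-10, and adjusted p = 0.225 with an estimated correlation). Psmd4 was at 0.60 ± 0.06 and Psmb7 at 0.59 ± 0.07. DNA replication genes (24 tested) included 16 that rose, 1 that fell and 7 not called (16 and 1 adjusted over the list alone). The median was 0.24 (adjusted p = 1.7e-05, and adjusted p = 0.0965 with an estimated correlation). The replicative helicase gene Mcm6 was at 0.44 ± 0.04 and its partner Mcm7 at 0.45 ± 0.04. Of 24 mitosis genes tested, 12 rose, 1 fell and 11 were not called (13 and 1 adjusted over the list alone). Their median was 0.16 (adjusted p = 6.2e-04, and adjusted p = 0.0965 with an estimated correlation). Among them were Birc5 (0.47 ± 0.08) and Aurka (0.33 ± 0.04). Replication-dependent histone genes (21 tested) included 15 that rose, 5 that fell and 1 not called (15 and 5 adjusted over the list alone). The median was 0.77 (adjusted p = 5.6e-05, and adjusted p = 0.130 with an estimated correlation). Of 22 hypoxia and glycolysis genes tested, 8 rose, 4 fell and 10 were not called (8 and 4 adjusted over the list alone). Their median was 0.17 (adjusted p = 0.0260, and adjusted p = 0.285 with an estimated correlation).

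The p53 target, interferon, pigmentation and Hippo lists were called lower at the preset correlation and not with an estimated one. Of 19 p53 targets tested, 1 rose, 12 fell and 6 were not called (1 and 12 adjusted over the list alone). The median was -0.43 (adjusted p = 6.2e-04, and adjusted p = 0.188 with an estimated correlation). Trp53inp1 was at -1.22 ± 0.08, Sesn2 at -0.95 ± 0.07 and Phlda3 at -0.82 ± 0.08. Type I interferon response genes (23 tested) included 0 that rose, 15 that fell and 8 not called (0 and 16 adjusted over the list alone). Their median was -0.49 (adjusted p = 6.2e-04, and adjusted p = 0.338 with an estimated correlation). These included Ifit1 (-1.45 ± 0.10), Ifit3 (-1.26 ± 0.10) and the signal transducer gene Stat2 (-1.06 ± 0.12). Of 19 pigmentation genes tested, 2 rose, 10 fell and 7 were not called (2 and 10 adjusted over the list alone). The median was -0.32 (adjusted p = 0.0104, and adjusted p = 0.0965 with an estimated correlation). Tyr was at -1.40 ± 0.06 and Dct at -0.82 ± 0.04. Hippo pathway components (22 tested) included 0 that rose, 14 that fell and 8 not called (0 and 14 adjusted over the list alone). Their median was -0.32 (adjusted p = 0.0122, and adjusted p = 0.428 with an estimated correlation). The immediate early list was not called (median log2 value -0.15, adjusted p = 0.514, and a median of 0.0062 with quantile normalization): Jun rose by 2.26 ± 0.07, while Ier3 (-1.84 ± 0.14), Myc (-1.36 ± 0.09) and Dusp6 (-1.04 ± 0.08) fell. Nfkbia, the gene of an NF-kB inhibitor, fell by 1.67, and Plekhm1 by 2.16. Kctd12, at 7.65 FPKM without heat under YAP/TAZ siRNA, was listed at 0 in all heated libraries of both siRNAs, which in an FPKM table can be a failed estimate. Among markers of other cell types Cd68 was higher (0.71 ± 0.14), while Cd79a, Pdgfrb and Lyz2 were not called (Lyz2 was with quantile normalization).

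Of 12626 genes, 2347 rose and 3999 fell with heat under YAP/TAZ siRNA (118 and 196 by at least 2-fold), with a median of -0.086. The split was 1413 and 5829 with every library scaled to 1 total (median -0.22), and 2729 and 2871 with quantile normalization, the setting in which the Hspd1 call ended. Calls of the interferon list ended with the filter at 5 FPKM, of the hypoxia list with that filter, without a filter and with quantile normalization, and of the mitochondrial chaperone list with quantile normalization, while Hsf1, higher by 0.24 ± 0.05, was not called with 1 total.

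The 2 heat responses were then compared gene by gene. An interaction below 0 is a smaller rise or a larger fall with heat under YAP/TAZ siRNA than under control siRNA, and one above 0 is the reverse. The inducible chaperones rose less under YAP/TAZ siRNA, and the immediate early and p53 target lists lay below 0, while cell cycle and ribosomal protein lists lay above 0 (the ribosomal protein call ended with an estimated correlation). Atf3 went from 1.42 ± 0.267 to 65.1 ± 12.6 FPKM with heat under control siRNA (SD, n = 3 and 2) and from 3.97 ± 0.0852 to 6.17 ± 0.0964 FPKM under YAP/TAZ siRNA (SD, n = 3 each), an interaction of -4.24 ± 0.15 (adjusted p = 8.2e-07). The interaction was -4.11 ± 0.58 for summed Hspa1a and Hspa1b (adjusted p = 6.7e-04), -3.94 ± 0.36 for Hspb1 (adjusted p = 6.6e-05), -2.51 ± 0.12 for Dnajb1 (adjusted p = 3.3e-06) and -1.40 ± 0.11 for Bag3 (adjusted p = 3.0e-05). It was smaller for Hsph1 (-0.60 ± 0.10) and Hsp90aa1 (-0.54 ± 0.07), and above 0 for Hsf1, the master regulator of the heat shock response (0.41 ± 0.08).

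Of 37 heat shock chaperones tested, 6 had an interaction above 0, 16 had one below 0 and 15 were not called (8 and 17 adjusted over the list alone). The median was -0.30 (adjusted p = 5.0e-04, and adjusted p = 0.165 with an estimated correlation). Immediate early genes (24 tested) had a called interaction above 0 in 0, below 0 in 19 and none in 5 (1 and 19 adjusted over the list alone). Their median was -1.13 (adjusted p = 2.2e-14, and adjusted p = 0.0367 with an estimated correlation). Among them were Btg2 (-3.54 ± 0.12) and Klf6 (-2.31 ± 0.13). Of 19 p53 targets tested, 0 had an interaction above 0, 16 had one below 0 and 3 were not called (0 and 16 adjusted over the list alone). The median was -1.16 (adjusted p = 4.8e-13, and adjusted p = 0.0308 with an estimated correlation). Trp53inp1 was at -3.70 ± 0.13, the pro-apoptotic gene Bbc3 at -3.67 ± 0.14, Sesn2 at -3.11 ± 0.11 and Mdm2 at -1.92 ± 0.07. Integrated stress response genes (23 tested) had a called interaction above 0 in 4, below 0 in 10 and none in 9 (4 and 11 adjusted over the list alone). Their median was -0.24 (adjusted p = 1.9e-04, and adjusted p = 0.165 with an estimated correlation). Ddit4 was at -2.91 ± 0.14. Of 16 YAP/TAZ-TEAD targets tested, 1 had an interaction above 0, 6 had one below 0 and 9 were not called (1 and 6 adjusted over the list alone). The median was -0.13 (adjusted p = 0.00614, and adjusted p = 0.165 with an estimated correlation). Ccn1 was at -1.13 ± 0.14 (-0.73 with a pseudocount of 0.1) and Ccn2 at -1.50 ± 0.11 (further from 0 with that pseudocount). Pgf, a growth factor of the VEGF family, had an interaction of -3.54 ± 0.19 (adjusted p = 5.6e-06).

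Immune lists also had interactions below 0, called at the preset correlation and by fry but not with an estimated correlation. The interferon list had a median of 0.17 with heat under control siRNA (not called) and -0.49 under YAP/TAZ siRNA (called, but not with an estimated correlation). Against control siRNA its median was 1.06 without heat (not called with an estimated correlation) and 0.33 after heat. The value after heat was not called (adjusted p = 0.391), except without a filter. Type I interferon response genes (23 tested) had a called interaction above 0 in 0, below 0 in 14 and none in 9 (0 and 16 adjusted over the list alone). Their median was -0.62 (adjusted p = 1.2e-06, and adjusted p = 0.165 with an estimated correlation). The chemokine gene Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) was at -2.48 ± 0.24. Of 8 MHC class I presentation genes tested, 0 had an interaction above 0, 4 had one below 0 and 4 were not called (0 and 4 adjusted over the list alone). The median was -0.28 (adjusted p = 0.00867, and adjusted p = 0.165 with an estimated correlation). H2-K1 was at -0.77 ± 0.12. Of the few low-level markers of other cell types tested, Cd68 was at -0.89 ± 0.21 (not called with a pseudocount of 0.1 or without heated control replicate 1). Cd79a was at -1.06 ± 0.14 (not called with that pseudocount), while Pdgfrb was at 0.42 ± 0.09 and Lyz2 was not called. Cytokine and NF-kB genes (8 tested) had a called interaction above 0 in 0, below 0 in 4 and none in 4 (0 and 4 adjusted over the list alone). Their median was -0.32 (adjusted p = 0.00615, and adjusted p = 0.0940 with an estimated correlation). Of 13 mitochondrially encoded mRNAs tested, 0 had an interaction above 0, 7 had one below 0 and 6 were not called (0 and 9 adjusted over the list alone). The median was -0.38 (adjusted p = 5.6e-05, and adjusted p = 0.165 with an estimated correlation). Of 22 Hippo pathway components tested, 1 had an interaction above 0, 7 had one below 0 and 14 were not called (1 and 7 adjusted over the list alone). Their median was -0.10 (adjusted p = 0.0197, and adjusted p = 0.440 with an estimated correlation). The Hippo list had nearby medians of -0.20 with heat under control siRNA and -0.32 under YAP/TAZ siRNA.

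The lists with interactions above 0 were led by DNA replication, mitosis and ribosomal protein genes. DNA replication and mitosis genes turned from lower with heat under control siRNA (medians -0.44 and -0.32) to higher under YAP/TAZ siRNA (0.24 and 0.16), though none of these 4 heat calls held with an estimated correlation. With median-of-ratios scaling the mitosis median with heat under control siRNA was -0.12 and was not called. Without heat both lists were already lower under YAP/TAZ siRNA (medians -0.58 and -0.65 against control siRNA). After heat the DNA replication list was not called between the siRNAs (median 0.093, adjusted p = 0.474), except without a filter. Its median there was -0.057 with median-of-ratios scaling. The mitosis median after heat was -0.17, not called with an estimated correlation. DNA replication genes (24 tested) had a called interaction above 0 in 22, below 0 in 0 and none in 2 (23 and 0 adjusted over the list alone). The median was 0.65 (adjusted p = 3.7e-10, and adjusted p = 0.0308 with an estimated correlation). Uhrf1 was at 1.38 ± 0.06 and Mcm5 at 0.94 ± 0.06. Of 24 mitosis genes tested, 18 had an interaction above 0, 0 had one below 0 and 6 were not called (20 and 0 adjusted over the list alone). Their median was 0.48 (adjusted p = 1.2e-06, and adjusted p = 0.0308 with an estimated correlation). Plk1 was at 1.02 ± 0.08 and Ccnb1 at 0.90 ± 0.06. Ribosomal protein genes (84 tested) had a called interaction above 0 in 63, below 0 in 0 and none in 21 (71 and 0 adjusted over the list alone). The median was 0.63 (adjusted p = 4.8e-11, and adjusted p = 0.292 with an estimated correlation). Rps4x was at 0.68 ± 0.10 and Rpl10a at 0.66 ± 0.10. Of 35 proteasome subunits tested, 22 had an interaction above 0, 0 had one below 0 and 13 were not called (25 and 1 adjusted over the list alone). Their median was 0.36 (adjusted p = 3.0e-04, and adjusted p = 0.371 with an estimated correlation). Of 8 chaperonin ring subunits tested, 7 had an interaction above 0, 0 had one below 0 and 1 was not called (7 and 0 adjusted over the list alone). The median was 0.34 (adjusted p = 0.00349, and adjusted p = 0.224 with an estimated correlation), and Cct5 was at 0.50 ± 0.07. Cholesterol synthesis genes (20 tested) had a called interaction above 0 in 12, below 0 in 0 and none in 8 (13 and 0 adjusted over the list alone). Their median was 0.36 (adjusted p = 0.00239, and adjusted p = 0.165 with an estimated correlation). Mvd was at 0.92 ± 0.11 and Nsdhl at 0.70 ± 0.08. The heat response of the list was less negative under YAP/TAZ siRNA (median -0.25 against -0.55 under control siRNA). Of 22 hypoxia and glycolysis genes tested, 12 had an interaction above 0, 2 had one below 0 and 8 were not called (13 and 2 adjusted over the list alone). The median was 0.36 (adjusted p = 0.0242, and adjusted p = 0.224 with an estimated correlation).

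**Figure D2:**
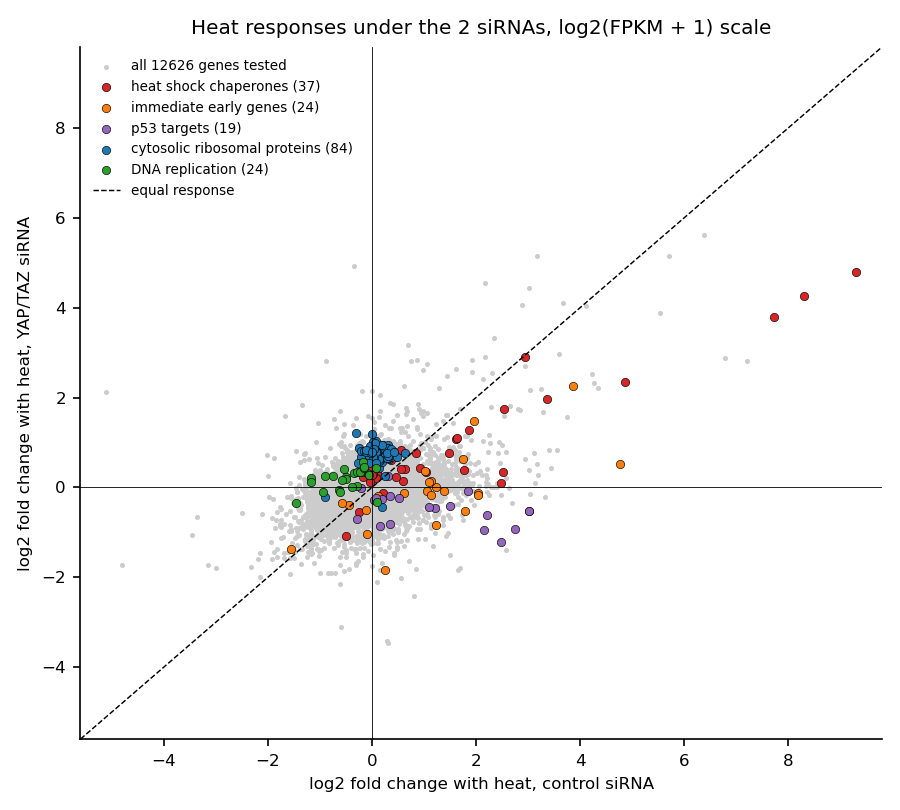
Log2 fold change with heat under control siRNA (horizontal axis) and under YAP/TAZ siRNA (vertical axis), log2(FPKM + 1) scale, 1 point per tested gene, with 5 gene lists in colour and a dashed line at equal responses. Across genes the Pearson r was 0.44, and 19 of 24 immediate early genes and 16 of 19 p53 targets had a called lower response under YAP/TAZ siRNA.

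Over all 12626 genes, 3102 had a larger or less negative heat response under YAP/TAZ siRNA and 1689 a smaller or more negative one (161 and 484 by at least 2-fold). Across genes, which are not independent replicates, the 2 heat responses had a Pearson r of 0.44 and a Spearman rho of 0.37, and data simulated with no interaction gave a Pearson r of 0.80 to 0.87. Both responses called 573 genes higher, where independent lists of those lengths would share 290, and 2335 genes lower, against 1474. In turn, 324 genes rose under control siRNA and fell under YAP/TAZ siRNA against 494 for independent lists. Among the 2197 genes called higher by the weighted mean of both responses, 910 (41.4%) responded less under YAP/TAZ siRNA, where simulations with no interaction gave 47.2 to 53.9%. That share was 71.4% among genes raised at least 2-fold, 66.2% without a filter and 50.8% with libraries scaled to 1 total. The simulated noise was independent between genes, while the ribosomal protein genes, for example, had an estimated correlation of 0.53. The simulated ranges are therefore too narrow, and the share of 41.4% cannot be judged against its range.

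With median-of-ratios scaling the split of the interaction was 1865 higher and 2307 lower, the median of all genes moving from 0.11 to -0.0053, and without heated control replicate 1 it was 2019 and 963, with 26.4% of heat-induced genes responding less (28.6% without heated control replicate 3). List calls ended without a filter (Hippo components), with the filter at 5 FPKM (hypoxia), with quantile normalization (chaperonin, cholesterol, hypoxia), without heated control replicate 3 (hypoxia) and without heated control replicate 1 (NF-kB, whose median was then -0.025). Single libraries left out also moved the medians of Hippo components (-0.025 without unheated control replicate 3 to -0.26 without heated YAP/TAZ siRNA replicate 2) and MHC class I genes (-0.44 without unheated YAP/TAZ siRNA replicate 2).

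Without heat, YAP/TAZ siRNA lowered the YAP target genes Ccn1 and Ccn2 and most genes of the mitosis and DNA replication lists. Ccn1 fell from 13.8 ± 0.561 to 1.52 ± 0.199 FPKM (SD, n = 3 each), by 2.56 on the log2 scale (adjusted p = 2.4e-07), and Ccn2 was at -1.85 ± 0.08 (adjusted p = 2.7e-07). YAP/TAZ-TEAD targets (16 tested) included 3 that rose, 8 that fell and 5 not called (4 and 8 adjusted over the list alone). Their median was -0.25 (adjusted p = 0.0391, and adjusted p = 0.204 with an estimated correlation). The coagulation factor receptor gene F3 was lower (-0.70 ± 0.06) and Tgfb2 higher (0.97 ± 0.09). Of 22 Hippo pathway components tested, 2 rose, 9 fell and 11 were not called (2 and 9 adjusted over the list alone). The median was -0.16 (adjusted p = 0.0175, and adjusted p = 0.504 with an estimated correlation). Among them were Wwc1 (-1.54 ± 0.05), Vgll3 (-2.04 ± 0.37), Lats2 (-0.87 ± 0.10) and Amotl2 (-0.60 ± 0.06). SRF and cytoskeleton targets (14 tested) included 2 that rose, 10 that fell and 2 not called (2 and 10 adjusted over the list alone). Their median was -0.35 (adjusted p = 0.00312, and adjusted p = 0.0696 with an estimated correlation). The myosin light chain gene Myl9 was at -1.81 ± 0.13 and the tropomyosin gene Tpm1 at -1.08 ± 0.05. Of 14 extracellular matrix genes tested, 2 rose, 8 fell and 4 were not called (2 and 8 adjusted over the list alone). The median was -0.25 (adjusted p = 0.0130, and adjusted p = 0.169 with an estimated correlation). These included Thbs1 (-1.14 ± 0.08) and Sparc (-0.98 ± 0.06). The fibroblast marker Pdgfrb was lower too (-0.69 ± 0.06), as was the macrophage marker Lyz2 (-0.34 ± 0.10, not called without a filter or without unheated control replicate 2 or unheated YAP/TAZ siRNA replicate 1), while Cd68 and Cd79a were not called.

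Mitosis genes (24 tested) included 0 that rose, 24 that fell and 0 not called (0 and 24 adjusted over the list alone). Their median was -0.65 (adjusted p = 2.8e-13, and adjusted p = 0.00920 with an estimated correlation). The kinase gene Aurka was at -0.91 ± 0.04 and the kinesin gene Kif20a at -0.90 ± 0.04. Of 24 DNA replication genes tested, 0 rose, 21 fell and 3 were not called (0 and 22 adjusted over the list alone). The median was -0.58 (adjusted p = 1.1e-11, and adjusted p = 0.0155 with an estimated correlation). Rrm2 was at -1.22 ± 0.05 and Mcm3 at -0.69 ± 0.03. Heat shock chaperones (37 tested) included 2 that rose, 18 that fell and 17 not called (2 and 18 adjusted over the list alone). Their median was -0.29 (adjusted p = 7.2e-05, and adjusted p = 0.112 with an estimated correlation). Hsp90aa1 went from 525 ± 17.0 to 249.9 ± 9.13 FPKM (SD, n = 3 each, -1.07 ± 0.05). Hsph1 was at -1.10 ± 0.07, Hspa8 at -0.78 ± 0.04, Ahsa1 at -0.80 ± 0.04 and Hsf1 (ENSMUSG00000022556, chromosome 15, 76477422 to 76501913) at -0.55 ± 0.05. Hspb1, Bag3 and the Hsp70 genes were not called for the siRNA without heat, with -0.35 ± 0.24 for Hspb1, 0.018 ± 0.07 for Bag3 and 0.38 ± 0.38 for summed Hspa1a and Hspa1b. Dnajb1 was lower (-0.26 ± 0.08), a call that ended with quantile normalization and without unheated control replicate 1 or 3 or unheated YAP/TAZ siRNA replicate 2. Of 8 chaperonin ring subunits tested, 0 rose, 8 fell and 0 were not called (0 and 8 adjusted over the list alone). The median was -0.58 (adjusted p = 4.2e-06, and adjusted p = 0.109 with an estimated correlation). Cct7 was at -0.59 ± 0.03. Mitochondrial chaperones and proteases (12 tested) included 1 that rose, 7 that fell and 4 not called (1 and 8 adjusted over the list alone). Their median was -0.21 (adjusted p = 0.00915, and adjusted p = 0.146 with an estimated correlation). Hspd1 was at -1.18 ± 0.05. Of 35 proteasome subunits tested, 0 rose, 25 fell and 10 were not called (0 and 28 adjusted over the list alone). The median was -0.24 (adjusted p = 2.1e-06, and adjusted p = 0.298 with an estimated correlation). Of 84 ribosomal protein genes tested, 0 rose, 26 fell and 58 were not called (0 and 19 adjusted over the list alone). Their median was -0.21 (adjusted p = 1.1e-05, and adjusted p = 0.504 with an estimated correlation). Of 16 NRF2 antioxidant targets tested, 2 rose, 11 fell and 3 were not called (2 and 11 adjusted over the list alone). The median was -0.46 (adjusted p = 0.00119, and adjusted p = 0.0748 with an estimated correlation). The thioredoxin reductase gene Txnrd1 was at -0.85 ± 0.05.

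Type I interferon response genes (23 tested) included 16 that rose, 1 that fell and 6 not called (16 and 1 adjusted over the list alone). Their median was 1.06 (adjusted p = 1.1e-05, and adjusted p = 0.201 with an estimated correlation). Examples were Ifit3 (1.35 ± 0.10) and Parp14 (1.35 ± 0.09), while Cxcl10 fell by 1.98. Of 8 MHC class I presentation genes tested, 7 rose, 0 fell and 1 was not called (7 and 0 adjusted over the list alone). The median was 0.88 (adjusted p = 3.9e-04, and adjusted p = 0.0891 with an estimated correlation). H2-K1, a class I heavy chain gene, rose from 1.90 ± 0.145 to 9.74 ± 0.857 FPKM (SD, n = 3 each, 1.89 ± 0.08, adjusted p = 2.7e-07) and B2m by 1.36 ± 0.07. The NF-kB subunit gene Relb rose by 1.54 ± 0.09, while the cytokine and NF-kB list that holds it was not called. Its median was -0.088 (adjusted p = 0.959, camera), with 3 of 8 genes higher and 3 lower. Pigmentation genes (19 tested) included 12 that rose, 3 that fell and 4 not called (12 and 4 adjusted over the list alone). Their median was 0.43 (adjusted p = 0.00352, and adjusted p = 0.0696 with an estimated correlation). Tyr was at 0.91 ± 0.06 and Dct at 0.90 ± 0.04. Of 20 cholesterol synthesis genes tested, 13 rose, 0 fell and 7 were not called (14 and 0 adjusted over the list alone). The median was 0.25 (adjusted p = 0.00112, and adjusted p = 0.112 with an estimated correlation). Hmgcs1 was at 0.50 ± 0.05. Mitochondrially encoded mRNAs (13 tested) included 6 that rose, 0 that fell and 7 not called (6 and 0 adjusted over the list alone). Their median was 0.15 (adjusted p = 0.0450, and adjusted p = 0.504 with an estimated correlation). The highest named genes were Mgll, which encodes monoacylglycerol lipase (2.71 ± 0.09, adjusted p = 1.5e-07), Scrg1 (2.69 ± 0.11), Pik3r3 (2.28 ± 0.08) and S100b (2.22 ± 0.07). The lowest were the thyroglobulin gene Tg (-2.71 ± 0.07, adjusted p = 5.4e-08), the protein kinase C theta gene Prkcq (-2.23 ± 0.05) and Igf2bp1 (-2.06 ± 0.08).

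Without heat 3420 genes were higher and 2761 lower under YAP/TAZ siRNA of 12626 tested (293 and 118 by at least 2-fold), with 2992 and 3003 under quantile normalization and 1842 and 2097 with the filter at 5 FPKM. List calls ended for Hippo components without unheated control replicate 2 or unheated YAP/TAZ siRNA replicate 3, for TEAD targets with library weights or without unheated YAP/TAZ siRNA replicate 3 (their median was 0.0070 without a filter), for extracellular matrix with the filter at 5 FPKM, where its median turned to 0.13, for mitochondrial chaperones with quantile normalization and for mitochondrial mRNAs under several settings (median 0.25 without unheated YAP/TAZ siRNA replicate 3).

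After heat, YAP/TAZ siRNA cells had lower levels of inducible chaperones, immediate early genes and p53 targets than control siRNA cells. Summed Hspa1a and Hspa1b stood at 201 ± 108 FPKM (SD, n = 3) against 2461 ± 63.9 FPKM (SD, n = 2), a difference of -3.73 ± 0.43 (adjusted p = 8.9e-05). Hspb1 was at -4.29 ± 0.27 (adjusted p = 2.5e-06), Dnajb1 at -2.78 ± 0.09 (adjusted p = 9.5e-08), Hsp90aa1 at -1.61 ± 0.05, Hsph1 at -1.69 ± 0.08, Bag3 at -1.38 ± 0.08 and the co-chaperone gene Chordc1 at -1.22 ± 0.06. Of 37 heat shock chaperones tested, 2 rose, 26 fell and 9 were not called (2 and 28 adjusted over the list alone). The median was -0.51 (adjusted p = 9.9e-12, and adjusted p = 0.0364 with an estimated correlation). Immediate early genes (24 tested) included 1 that rose, 21 that fell and 2 not called (1 and 21 adjusted over the list alone). Their median was -1.14 (adjusted p = 1.9e-14, and adjusted p = 0.0364 with an estimated correlation). Btg2 was at -3.84 ± 0.09 (adjusted p = 1.9e-08), Atf3 at -3.19 ± 0.12 and Maff at -2.04 ± 0.09. Of 19 p53 targets tested, 1 rose, 16 fell and 2 were not called (1 and 18 adjusted over the list alone). The median was -1.60 (adjusted p = 6.0e-13, and adjusted p = 0.0364 with an estimated correlation). Among them were the kinase gene Plk2 (-3.11 ± 0.11), Mdm2 (-2.39 ± 0.06) and Sesn2 (-2.27 ± 0.08).

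YAP/TAZ-TEAD targets (16 tested) included 3 that rose, 8 that fell and 5 not called (3 and 8 adjusted over the list alone). Their median was -0.35 (adjusted p = 0.00116, and adjusted p = 0.0702 with an estimated correlation). Ccn1 was at -3.69 ± 0.11 (adjusted p = 8.6e-08) and Ccn2 at -3.35 ± 0.09 (adjusted p = 2.9e-08). Of 22 Hippo pathway components tested, 1 rose, 12 fell and 9 were not called (2 and 13 adjusted over the list alone). The median was -0.41 (adjusted p = 2.0e-05, and adjusted p = 0.186 with an estimated correlation). These included Amotl2 (-1.43 ± 0.07) and Lats2 (-1.29 ± 0.11). NRF2 antioxidant targets (16 tested) included 1 that rose, 8 that fell and 7 not called (1 and 9 adjusted over the list alone). Their median was -0.51 (adjusted p = 3.8e-05, and adjusted p = 0.0364 with an estimated correlation). Txnrd1 was at -1.48 ± 0.06, Hmox1 at -1.47 ± 0.07 and the cystine transporter gene Slc7a11 at -1.19 ± 0.08. Of 23 integrated stress response genes tested, 5 rose, 13 fell and 5 were not called (5 and 13 adjusted over the list alone). The median was -0.42 (adjusted p = 0.00115, and adjusted p = 0.164 with an estimated correlation). SRF and cytoskeleton targets (14 tested) included 1 that rose, 7 that fell and 6 not called (1 and 7 adjusted over the list alone). Their median was -0.39 (adjusted p = 0.00192, and adjusted p = 0.0394 with an estimated correlation). Tpm1 was at -0.74 ± 0.06 and Actg1 at 0.64 ± 0.05. Of 14 extracellular matrix genes tested, 2 rose, 8 fell and 4 were not called (2 and 8 adjusted over the list alone). The median was -0.34 (adjusted p = 0.00126, and adjusted p = 0.0830 with an estimated correlation). Of the markers of other cell types, Cd68 was at -1.08 ± 0.16, Cd79a at -1.25 ± 0.11, Pdgfrb at -0.27 ± 0.07 (not called without heated control replicate 1) and Lyz2 at -0.34 ± 0.11 (not called without a filter, with only the groups compared, or without heated control replicate 3, at -0.16, or heated YAP/TAZ siRNA replicate 2 or 3). Cxcl10 (-4.46 ± 0.18, adjusted p = 2.6e-07) and Pgf (-3.44 ± 0.14) were among the lowest genes. Mitosis genes (24 tested) included 4 that rose, 11 that fell and 9 not called (4 and 12 adjusted over the list alone). Their median was -0.17 (adjusted p = 0.00367, and adjusted p = 0.0862 with an estimated correlation). Of 8 chaperonin ring subunits tested, 0 rose, 6 fell and 2 were not called (0 and 7 adjusted over the list alone). The median was -0.23 (adjusted p = 0.00132, and adjusted p = 0.186 with an estimated correlation). Of 8 cytokine and NF-kB genes tested, 2 rose, 4 fell and 2 were not called (2 and 6 adjusted over the list alone). Their median was -0.44 (adjusted p = 0.0210, and adjusted p = 0.0862 with an estimated correlation).

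The cholesterol synthesis, pigmentation, MHC class I and ribosomal protein lists were called higher, and the calls of the last 2 ended with an estimated correlation. Of 20 cholesterol synthesis genes tested, 20 rose, 0 fell and 0 were not called (20 and 0 adjusted over the list alone). The median was 0.56 (adjusted p = 3.4e-06, and adjusted p = 0.0394 with an estimated correlation). Mvd was at 1.30 ± 0.08 and Hmgcs1 at 0.99 ± 0.05. Pigmentation genes (19 tested) included 15 that rose, 2 that fell and 2 not called (15 and 2 adjusted over the list alone). Their median was 0.46 (adjusted p = 0.00367, and adjusted p = 0.0426 with an estimated correlation). Mc1r was at 0.98 ± 0.05 and the lineage factor gene Sox10 at 0.92 ± 0.05, while Tyrp1 was lower (-0.92 ± 0.09). Of 8 MHC class I presentation genes tested, 6 rose, 1 fell and 1 was not called (6 and 1 adjusted over the list alone). The median was 0.67 (adjusted p = 0.0266, and adjusted p = 0.186 with an estimated correlation). H2-K1 was at 1.12 ± 0.09 and B2m at 0.97 ± 0.08. Ribosomal protein genes (84 tested) included 51 that rose, 0 that fell and 33 not called (54 and 0 adjusted over the list alone). Their median was 0.41 (adjusted p = 8.2e-05, and adjusted p = 0.562 with an estimated correlation). Rps4x was at 0.67 ± 0.07. Mgll (2.73 ± 0.10), Scrg1 (2.72 ± 0.12) and the orphan receptor gene Gpr37 (2.51 ± 0.06) were the highest named genes.

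**Figure D3:**
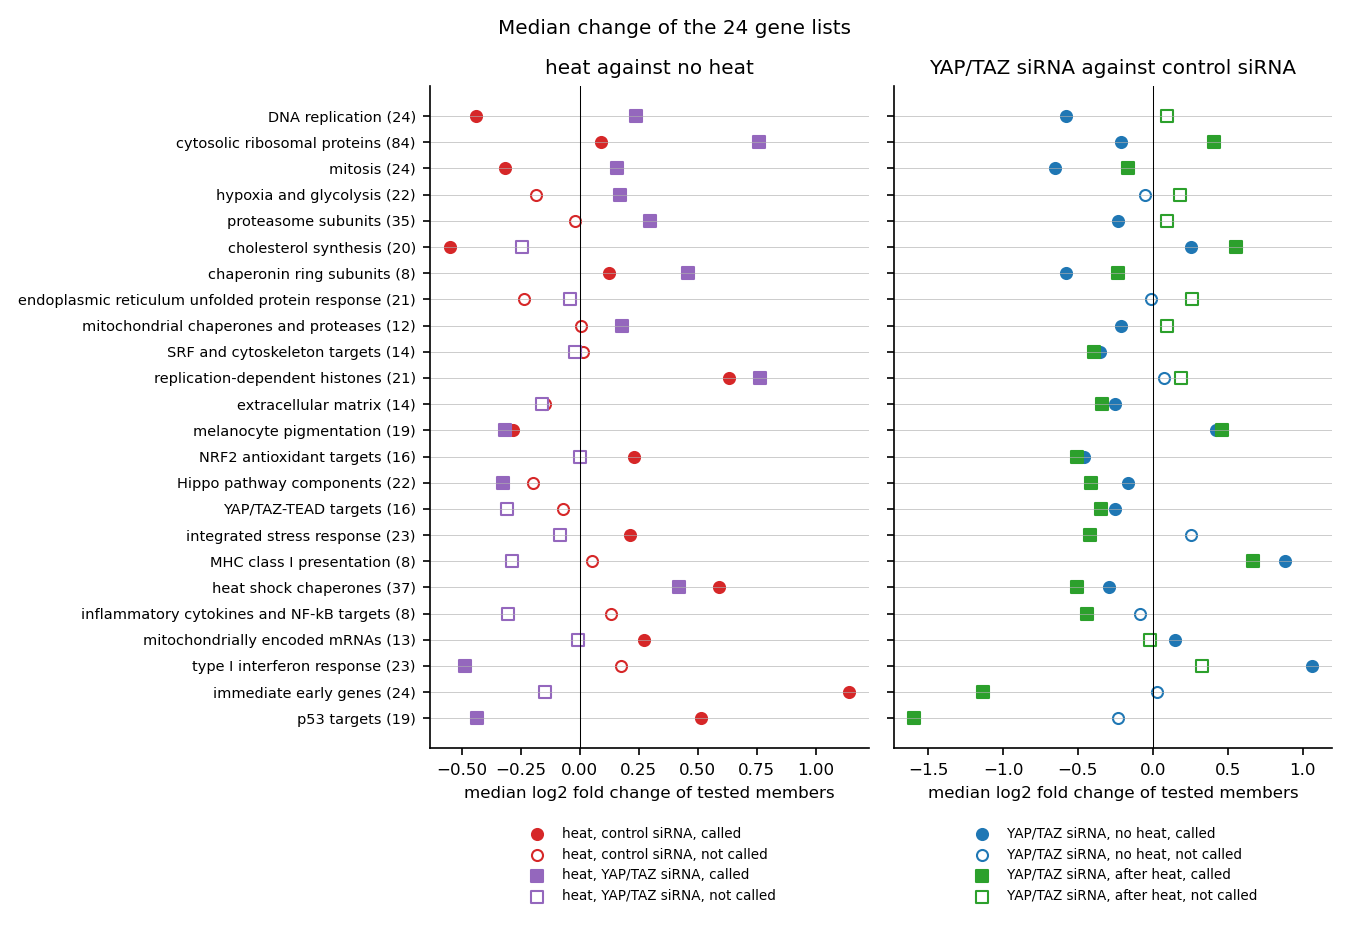
Median log2 fold change of the tested members of the 24 gene lists (number of members in brackets), for heat against no heat under each siRNA (left) and for YAP/TAZ siRNA against control siRNA without and after heat (right); filled markers are lists called by camera at the preset correlation. The p53 target median was 0.51 with heat under control siRNA and -0.43 under YAP/TAZ siRNA, and the ribosomal protein median was 0.089 and 0.76.

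After heat 4589 genes were higher and 2266 lower under YAP/TAZ siRNA (292 and 481 by at least 2-fold), with 3219 and 3299 under median-of-ratios scaling (median of all genes 0.0043 in place of 0.13) and 3707 and 2941 under quantile normalization. Without heated control replicate 1 there were 1429 lower genes, and list calls ended for extracellular matrix with the filter at 5 FPKM, where its median turned to 0.24, and for NF-kB genes without a filter (median -0.032) or without heated control replicate 1 (-0.22) or 3 (-0.33). Without heated control replicate 1 the integrated stress response median was -0.26.

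Of the 1560 genes that rose with heat under control siRNA, 1040 (66.7%) were lower under YAP/TAZ siRNA after heat, such as Hspb1, Dnajb1, Atf3, Btg2 and Ccn1, and 128 were higher. Independent lists would share 280 and 567 genes. Both comparisons use the same 2 heated control libraries, which gives an overlap with no effect at all. Lists of the same lengths drawn from simulated unchanged groups shared 811 to 901 genes. Such groups gave 0 called genes in common at the same threshold in limma, since adjusted p-values leave almost no calls where nothing changes. That count says nothing of the overlap that shared libraries add among genes that change. The covariance of the 2 sets of log2 changes was -0.195 against -0.0229 in those simulations, and the correlation was -0.598 against -0.597. Where the heated control libraries are divided or 1 is left out below, 1 library stands for that group and the spread comes from the other groups. With 1 heated control library used for heat and the other for the siRNA comparison, on 12262 genes that passed the filter in the other 9 libraries, the overlap was 528 and 494 genes where independent lists would share 108 and 107, and it was 609 and 480 with 1 library used for both. The overlap was 502 without heated control replicate 1, 635 without replicate 3 and 433 with the filter at 5 FPKM, against 2997 without a filter and 1769 with median-of-ratios scaling.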

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

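The tests of one common factor and of another effect of the siRNA pool were chosen only after the result was seen. All results in this part were singled out because the heat response differed between the 2 siRNAs by the interaction test, negative values marking a smaller or more negative response under YAP/TAZ siRNA. The genes that differed numbered 3102 above 0 and 1689 below 0.

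Of the 17 lists that differed, 4 held their call with an estimated correlation (immediate early genes, p53 targets, mitosis and DNA replication) and 13 did not. The 17 had median interactions of -0.30 (heat shock chaperones), -1.13 (immediate early genes), -1.16 (p53 targets), -0.24 (integrated stress response), -0.13 (YAP/TAZ-TEAD targets) and -0.10 (Hippo pathway components). Below 0 were also -0.62 (type I interferon response), -0.28 (MHC class I presentation), -0.32 (cytokine and NF-kB genes) and -0.38 (mitochondrially encoded mRNAs). Above 0 were 0.34 (chaperonin ring subunits), 0.48 (mitosis), 0.65 (DNA replication), 0.36 (cholesterol synthesis), 0.36 (hypoxia and glycolysis), 0.36 (proteasome subunits) and 0.63 (ribosomal protein genes).

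Among single genes, the heat shock genes that differed were Hspa1a (-4.52), Hspa1b (-4.04), Hspb1 (-3.94), Dnajb1 (-2.51), Bag3 (-1.40), Hsph1 (-0.60), Hsp90aa1 (-0.54) and Hsf1 (0.41). Stress and p53 genes were Atf3 (-4.24), Trp53inp1 (-3.70), Bbc3 (-3.67), Btg2 (-3.54), Sesn2 (-3.11), Ddit4 (-2.91), Klf6 (-2.31) and Mdm2 (-1.92). Secreted and immune genes were Pgf (-3.54), Cxcl10 (-2.48), Ccn1 (-1.13), Ccn2 (-1.50) and H2-K1 (-0.77). Genes above 0 were Uhrf1 (1.38), Mcm5 (0.94), Plk1 (1.02), Ccnb1 (0.90), Rps4x (0.68), Rpl10a (0.66), Cct5 (0.50), Nsdhl (0.70), Mvd (0.92), mt-Ty (2.50) and mt-Tc (2.07). Markers of other cell types, all at low levels, were Cd68 (-0.89), Cd79a (-1.06) and Pdgfrb (0.42).

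Heat shock chaperones, immediate early genes and p53 targets had a lower heat response under YAP/TAZ siRNA, with a median interaction of -0.65 over 79 tested members, 62 of them below 0. The chaperones alone had a median of -0.30, with 16 called below and 6 above 0, and their list call ended with an estimated correlation. Scaling between libraries is argued against, since the median of the 79 lay at -0.68 in whichever of 3 other scalings brought it nearest to 0. One common factor acting alone on the whole heat response is argued against too. Of the genes called by the weighted mean of both responses, at least 14.3% had a larger response under YAP/TAZ siRNA in each of 4 scalings. These were calls of the interaction test (1239 larger and 2006 smaller of 7378 as analysed). A generally weaker response beside changes of single genes is not excluded by that test. An effect of the siRNA pool other than on YAP and TAZ cannot be told apart from the knockdown, because 1 pool was used and interferon genes already differed without heat (median 1.06). A need for YAP and TAZ in this part of the heat response is a candidate explanation and stays untested against that one. All heated libraries were taken after 6 h of recovery, so differences in the timing of the response were not measured.

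Ribosomal protein genes rose with heat under YAP/TAZ siRNA more than under control siRNA, with a median interaction of 0.63 over 84 genes, a list call that ended with an estimated correlation (adjusted p = 0.292). Reads moving between these genes and their named pseudogenes are argued against, since the sum over 384 such genes had an interaction of 0.62 ± 0.13 (adjusted p = 6.7e-03, limma). After a trend on transcript length and level was removed the median was 0.30, with 77 of 84 genes above 0 and a standard error between libraries of 0.11 for the mean, which lies at the limit of 0.3 set for that test. Such a trend may therefore account for part of the difference. The 20 other genes nearest in length and level were taken for each of the 84 genes, and the median of their 84 medians was 0.41. Only the 84 genes were kept out of the trend and the neighbours. Named pseudogenes that passed the filter could enter both, and their sum over 300 genes had an interaction of 0.62 ± 0.14. Removing the trend may thus remove part of the difference itself, so this test cannot tell how much the trend accounts for. A change in ribosomal protein mRNA after YAP/TAZ knockdown also stays open, and was not tested.

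The 2 comparisons with 3 libraries on each side allow 10 splits each, too few for a share under 0.05. Heat under YAP/TAZ siRNA gave 6346 called genes and the highest other split 2, the real split being the 1 as large. YAP/TAZ siRNA without heat gave 6181 and the highest other split 2, again 1 as large. Each of the other splits mixed libraries of both real groups on each side, so a real difference widens the spread within them. Their few calls are therefore not the level of calls where nothing differs.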

How the results depend on the processing

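The fit without assembled loci and the division of the heated control libraries were chosen only after the results were seen. Dividing the 2 libraries between the comparisons, which leaves 1 library in each, gave an overlap of 528 and 494. Leaving out the assembled loci moved no count of calls beyond 1.5 times. Pseudocounts, fits without a trend or with robust variances, only the groups compared and library weights moved none either. The counts below give higher and then lower genes where both moved. Without a filter, 4117 genes were higher with heat under control siRNA, 3270 had a lower interaction and 4407 were lower under YAP/TAZ siRNA after heat. The overlap of heat-induced genes with genes lower under YAP/TAZ siRNA was 2997, and the share of heat-induced genes responding less turned to 66.2%. More genes enter that test. With the filter at a mean of 5 FPKM, which tests fewer genes, the counts were 755 and 2848 for heat under control siRNA, 2115 lower for heat under YAP/TAZ siRNA, 760 lower for the interaction, 1842 higher for YAP/TAZ siRNA without heat and 2926 and 1.2e+03 after heat. The share responding less was 24.9% and the overlap 433. With a 2-fold minimum, which calls fewer genes by construction, the counts were 475 and 298, 118 and 196, 161 and 484, 293 and 118, and 292 and 481 in the order of the comparisons, the share turned to 71.4% and the overlap was 303.

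With libraries scaled to 1 total, 1413 genes were higher with heat under YAP/TAZ siRNA and the share responding less turned to 50.8%. With median-of-ratios scaling the counts were 2891 and 2733 for heat under control siRNA and 1865 higher for the interaction, the share was 48.9% and the overlap 1769. Quantile normalization gave a share of 46.7%. The extracellular matrix median turned to 0.13 without heat and 0.24 after heat with the filter at 5 FPKM. Hsf1 with heat under control siRNA turned to 0.014 with median-of-ratios and 0.022 with quantile normalization. The cause of these moves was not tested. The correlation of the 2 heat responses and the Yap1 and Wwtr1 changes kept their direction in every setting run for them. Wwtr1 was below the filter at a mean of 5 FPKM and was not tested with it. Only leaving out heated control replicate 1 ended a Yap1 call.

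Leaving out each library in turn gave these ranges. Heat under control siRNA had 874 to 1611 higher and 3453 to 4754 lower genes. The interaction had 2019 to 3207 higher and 963 to 1808 lower genes, and YAP/TAZ siRNA after heat 1429 to 2329 lower genes. The share responding less was 26.4 to 48.7%, the overlap 502 to 1066 and the Yap1 change after heat -1.82 to -1.04. The lowest counts came without heated control replicate 1, which leaves 1 library assumed to vary like the other groups.

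With the replicate block, the counts were 1660 and 4803, 2452 and 4143, 3385 and 1909, 3560 and 2939, and 4710 and 2429 in the order of the comparisons, none beyond 1.5 times. The Hsf1 call for heat under control siRNA ended with the block, with the filter at 5 FPKM, with a 2-fold minimum and without any 1 of 7 libraries. The block added a call of the interferon list there, and changed no other call of a named gene. Deviations of libraries with the same number had correlations of -0.110 to 0.134 over 15 pairs, against -0.180 to 0.155 over 30 pairs with different numbers. Of 11 libraries, 5 correlated best with their own number. Deviations within such small groups mirror each other, so these values cannot tell whether libraries of the same number shared a day or batch. Gene set tests were not run without a trend, with robust variances, with only the groups compared or with the 2-fold minimum, and the fit of only the groups compared gives no interaction. Depth of 30.5 to 43.9 M fragments leaves values near 0.0228 to 0.0328 FPKM on a gene of 1 kb at the level of 1 fragment.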

Other observations

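The depth test of newly listed genes was chosen only after the result was seen. Rmrp, the RNA of the RNase MRP complex (ENSMUSG00000115420, chromosome 4, 43492783 to 43493063), went from 0.587 ± 0.212 to 55.8 ± 13.6 FPKM with heat under YAP/TAZ siRNA (SD, n = 3 each), a log2 change of 5.14 ± 0.16 (adjusted p = 2.8e-07, limma), and from 0.172 ± 0.0124 to 9.58 ± 1.56 FPKM under control siRNA (SD, n = 3 and 2). Rpph1, the RNA of RNase P (ENSMUSG00000092837, chromosome 14, 50807449 to 50807767), rose by 4.07 ± 0.18 under YAP/TAZ siRNA (adjusted p = 1.6e-06), to 22.5 ± 6.44 FPKM (SD, n = 3). The mitochondrial tRNA genes mt-Ty and mt-Tc rose under YAP/TAZ siRNA too, mt-Ty being at 3.18 ± 0.14 and mt-Tc at 2.82 ± 0.12. The interaction was 2.50 ± 0.21 for mt-Ty (adjusted p = 4.2e-05) and 2.07 ± 0.18 for mt-Tc. These genes are short, and FPKM of genes shorter than the sequenced fragments is uncertain.

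In control siRNA cells 1719 genes were listed at 0 in all 3 unheated libraries and above 0 in both heated ones, and 175 the other way. With equal numbers of libraries on both sides the counts were 1969 to 2100 against 289 to 316, a ratio of 6.27 to 7.16. Under YAP/TAZ siRNA 446 genes were newly listed and 169 lost. These rested on all 3 heated libraries rather than 2, a stricter rule, so the counts of the 2 siRNAs are not directly comparable. The difference between the siRNAs was not tested. The newly listed genes were low, with a median of 0.0791 FPKM, 65 above 1 FPKM and 0.109% of summed FPKM. Of 1672 with an annotated biotype, 892 (53.3%) were protein coding, 265 processed pseudogenes and 130 lincRNAs.

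For these genes listed at 0 without heat and above 0 after heat, deeper sequencing is argued against, since the deepest heated control library held 0.955 times the fragments of the shallowest unheated one. Genomic DNA or other signal spread without regard to gene ends is argued against as the only source. Of the newly listed genes, 273 overlapped expressed genes and were left out, and 1374 did not. Of the 1374, 548 (39.9%) lay within 20 kb past the 3' end of an expressed gene and 374 (27.2%) within 20 kb before a 5' start. The interval of the ratio of 548 to 374 (1.33 to 1.61, 1000 resamples) lay above 1. Spread signal beside another source is not excluded by that. Both shares were above those of all genes listed at 0 without heat (8.43 and 8.81%), and the cause of the excess before 5' starts was not tested. Transcription past the ends of expressed genes may contribute, but the ratio of 1.47 fell short of the 1.5 set for that test, and all genes listed at 0 without heat had a ratio of 0.958. Genes lost with heat had a ratio of 1.29 (0.75 to 2.44), too few to tell the directions apart, and under YAP/TAZ siRNA, outside that test, the ratio was 1.89 (1.52 to 2.42) for newly listed and 1.21 (0.80 to 1.86) for lost genes.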
